A study of Mus musculus with 6 samples.

How the data were processed

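RNA was sequenced from 6 cultures, 3 WT and 3 Stat3C, from 100 ng of input RNA each as stranded polyA libraries. The submitters' processing notes name cutadapt 3.4, Trimmomatic 0.39, Salmon 1.5.2, edgeR 3.34.1 and GRCm38, without the order or settings, and the annotation release was not given in the sources used here. The authors deposited a table of length-scaled estimated counts per gene (expected counts, not whole numbers), which sums to each library's total. Per the file headers, each library also had transcript-level expected counts from Salmon, with TPM values and effective lengths in bases. The authors deposited a further table of normalized CPM for 15588 genes, in which each library was the count table times 1 constant. This does not by itself show how its unit relates to plain CPM. Per the submitters' labels no batch was given, so that any difference in the handling of the libraries between genotypes coincides with the group.

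All 6 libraries were mapped to their samples, with 0 unmapped columns. Gene names, classes and coordinates came from GENCODE mouse release 21 on GRCm38, which held 51115 of the 51201 gene IDs, and 1 of 573 list symbols had no match. Rebuilding the length-scaled counts from the transcript values gave 92.7% of values within 5% of the deposited count. Deposited gene counts were rounded to whole numbers, filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with edgeR 4.0.16 quasi-likelihood tests (glmQLFTest, two-sided) under R 4.3.3. Adjusted p values are Benjamini-Hochberg values over the 15661 genes tested, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes are the size of the change divided by the square root of F. CPM in the text are TMM-normalised, with SD over the 3 libraries of a group. Gene lists were tested with camera (limma 3.58.1, inter-gene correlation preset to 0.01, two-sided), with adjustment over the 31 of 32 lists that had at least 3 tested genes. Of the 31 lists, 11 were called, 0 of them with a correlation estimated per list, where the smallest adjusted p was 0.450, and 14 were called by the directional fry test. Library-level measures were compared by exact two-sided permutation tests, whose smallest p with 3 against 3 is 0.1.

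The comparison, the gene lists, the tests and most alternatives were chosen before the data were examined. Genes named in the text were Stat3 and Gt(ROSA)26Sor, then the 12 called genes with the largest rise and the 12 with the largest fall among those with a mean of at least 5 CPM in the higher group and no overlap between groups. Predicted genes, immunoglobulin and T cell receptor segments and sex-linked genes were left out. In each list up to 6 called members of smallest adjusted p were added, and 10 genes central to TH17 biology were kept whether or not they passed, of which 1 is not reported here. A second selection of the 12 largest changes among protein-coding genes with at most 10% shared sequence, and a fit on those genes alone, were added after the data were seen. Some further genes, such as Egr1, Cd69, Irf7, H2-Aa, Hbb-bt and Gata2, are given with single values outside these rules. They are not in the counts of named genes. Shared sequence was the percentage of a gene's 31-base words also present in transcripts of other genes, computed with Python 3.11.15.

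A single count corresponded to between 0.0140 and 0.0385 CPM, and a group without counts was given a floor of 3 counts over the group. Such floors cover counting error only, whereas the SD and SE values also hold the spread between libraries. The within-library share of counts on the 10 most abundant genes was 8.75% in WT and 5.47% in Stat3C, and TMM factors averaged 0.951 and 1.05. The procedure was tested on simulated data with known changes at the depths and spread of these libraries. It called 4.48% of genes changed 1.5-fold, 25.4% of those changed 2-fold and 59.1% of those changed 4-fold, with median estimated folds of 1.47, 2.00 and 4.11, and 4.84% of its calls were unchanged genes. At these folds 67, 67 and 66 single genes were changed, far fewer than the 2192 called in the real comparison. The percentages therefore describe the simulation and may differ for the real fit. DESeq2 in the same simulation called more, and 38.9% of its calls were unchanged genes. A first version of this check required over 80% recovery of 4-fold changes, which was not met, and the requirement was replaced by one on the estimated folds.

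Alternatives tried were DESeq2 size factors, upper quartile scaling, no count filter, filters of 1 and 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, transcript reads summed per gene, limma-trend on the deposited CPM with pseudocounts of 1 and 0.1, leaving out each library, an adjusted p under 0.01, a fold of at least 2, glmTreat against a fold of 1.2, and other set tests. Effective lengths were read only to rebuild the counts. Marker lists of basophils and mast cells, neutrophils, and monocytes and macrophages were added after single genes of these kinds had been seen. Mcpt8 and Ly6g were left out of them, but 9 of 10 monocyte and macrophage markers, Cd68 and Mpeg1 among them, and 2 neutrophil markers were already in lists fixed beforehand.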

Results

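Gene expression was measured by polyA RNA sequencing in CD4 T cells cultured from C57BL/6J mice. Naive cells taken from the spleen at day 35 were activated for 2 days through CD3 and CD28 with interferon gamma and IL-4 blocked, and received IL-6, IL-1 beta and IL-23 at 20 ng/ml each, a mixture that the labels call pathogenic TH17. TH17 cells are helper T cells that make IL-17. The 3 wild-type (WT) cultures were replicates 1 to 3, and the 3 Stat3C cultures were replicates 4 to 6. Stat3C is a constitutively active form of STAT3, the transcription factor downstream of gp130 cytokines such as IL-6, and in these mice Cre recombinase driven by Cd4 removes a stop sequence placed before it. Total counts were 40921500, 74354100 and 66074000 in WT replicates 1, 2 and 3. They were 55607400, 47319800 and 25066800 in Stat3C replicates 4, 5 and 6. WT replicate 3 and Stat3C replicate 6 held Xist at 436 and 486 CPM (normalised counts, scaled to library size) and no Ddx3y count, while Xist was at most 0.148 CPM in the other 4 libraries.

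Stat3C was compared with WT under TH17 conditions. The labels do not state whether the WT mice carried Cre, so any effect of Cre itself coincides with that of the Stat3C allele in every difference between the groups. Stat3 itself (ENSMUSG00000004040, GRCm38 chromosome 11, 100885098 to 100939540) rose from 274 ± 24.6 CPM in WT to 1155 ± 105 CPM in Stat3C (SD, n = 3 in each group), a log2 fold change of 2.08 ± 0.10 (SE, adjusted p = 0.000162). The transcript of the Rosa26 locus, Gt(ROSA)26Sor (ENSMUSG00000086429, chromosome 6, 113067428 to 113077333), a common insertion site for conditional transgenes, went the other way. It changed from 2.07 ± 0.310 to 0.505 ± 0.0966 CPM and fell by 2.04 ± 0.30 (SE) on the log2 scale (adjusted p = 0.00845). Estimated Stat3 transcripts with a 3' UTR of at least 1000 bases averaged 52.3 ± 2.91 TPM in WT and 96.6 ± 5.46 TPM in Stat3C, while the remaining Stat3 models averaged 24.3 ± 8.63 and 313 ± 24.5 TPM (SD, n = 3). Those remaining models took 7.45% ± 1.45 of Stat3 reads in WT and 40.9% ± 3.88 in Stat3C (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). When transcript reads were summed per gene without length scaling, the log2 fold change of Stat3 was 1.25.

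In edgeR's quasi-likelihood test, 984 of 15661 genes were higher in Stat3C and 1208 were lower at an adjusted p under 0.05, and 438 and 687 of these changed by at least 2-fold. In all, 2192 genes were called. Both groups separated on the first principal component, which held 49.7% of the variance, and WT replicate 1 stood apart on the second (17.3% of the variance), at 86.0 against -22.8 and -41.9 in the other WT libraries. Leaving out WT replicate 2, WT replicate 3, or Stat3C replicate 4, 5 or 6 lowered the number called to 1230, 1351, 1201, 1309 and 1303, whereas 2013 were called without WT replicate 1.

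TH17 genes were higher in Stat3C. Il17f (ENSMUSG00000041872, chromosome 1, 20777146 to 20790617), a TH17 cytokine, rose from 12.3 ± 8.28 to 420 ± 66.0 CPM (SD, n = 3), a log2 fold change of 5.09 ± 0.52 (SE, adjusted p = 0.00236). Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496) rose from 6.45 ± 6.73 to 129 ± 27.5 CPM (4.32 ± 0.80, adjusted p = 0.0188). Receptor genes for IL-23 and IL-1 rose too, Il23r from 2.13 to 16.4 CPM (2.94 ± 0.42) and Il1r1 from 5.78 to 48.6 CPM (3.07 ± 0.22). The transcription factor gene Maf rose by 2.82 ± 0.42, from 2.68 ± 1.49 to 19.1 ± 1.07 CPM (adjusted p = 0.00893). Of 22 tested TH17 identity genes, 15 were higher, 0 lower and 7 not called, or 16 and 0 when adjusted over the list alone. The TH17 identity list had a camera adjusted p = 1.14e-10, and an adjusted p = 0.450 with an estimated correlation. Stat3C replicate 5, also the highest library for 8 of 9 tested myeloid marker genes, had the highest value for 11 of the 22 genes, and without it the list had a median log2 fold change of 1.07 (adjusted p = 9.57e-11). Without WT replicate 3 the log2 fold changes of Il17a, Il17f and Il23r became 5.62, 5.81 and 3.56. The call for Il17a was lost without WT replicate 2, Stat3C replicate 5 or Stat3C replicate 6 (adjusted p = 0.0660, 0.0558 and 0.0580). Il22 rose from 7.59 ± 8.30 to 109 ± 72.6 CPM (adjusted p = 0.0438), with 53.6% of its sequence words also in other genes. Stat3C replicate 5 stood at 193 CPM of Il22, against 64.3 and 69.5 CPM in the other Stat3C libraries. With single libraries left out, the Il22 call held only without WT replicate 3 (highest adjusted p = 0.123). Its log2 fold change went from 3.83 to 5.26 without that library and to 3.15 without Stat3C replicate 5.

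**Figure D1:**
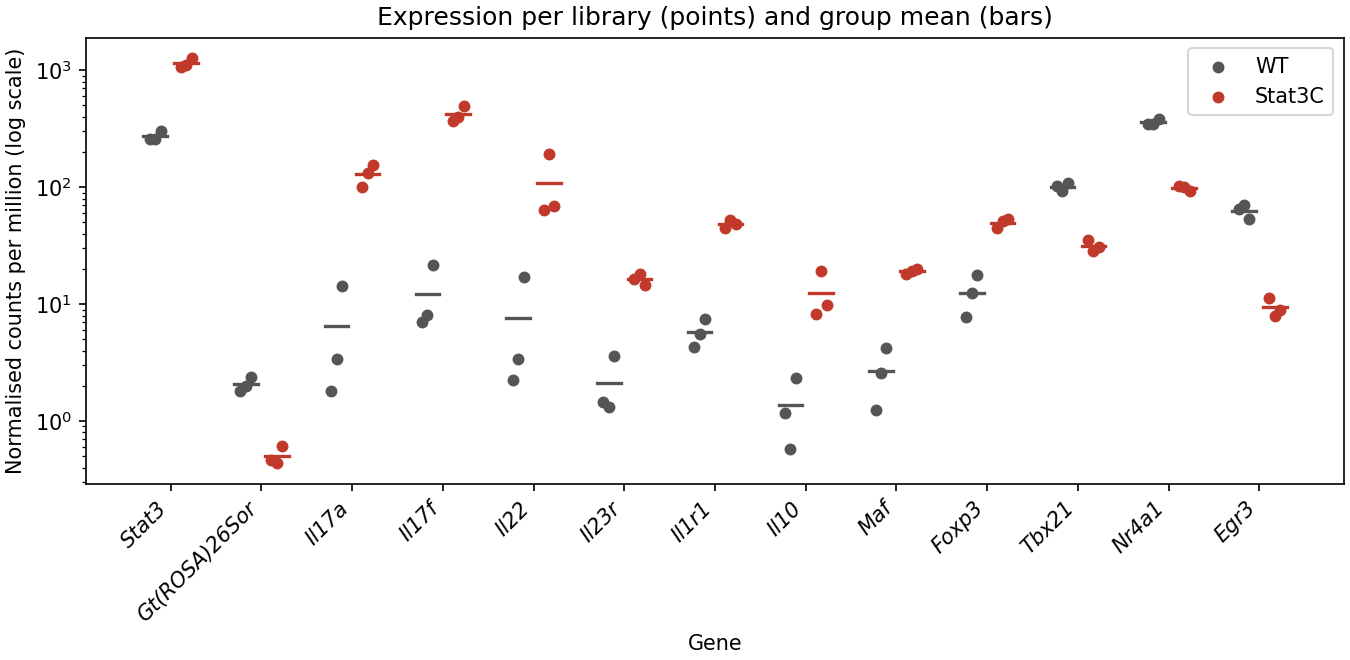
Normalised counts (CPM) on a log scale for 13 genes in each of the 3 WT and 3 Stat3C libraries (points), with the group mean as a bar. Stat3 averaged 274 CPM in WT and 1155 CPM in Stat3C, and Il17f 12.3 and 420 CPM, with no overlap between the groups.

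Genes linked to regulatory T cells and to non-pathogenic TH17 cells were also higher in Stat3C. Several lists share members, so their calls are not independent. Maf and Ahr are in both the TH17 identity and the non-pathogenic TH17 list, and Il10 in both the regulatory and the non-pathogenic list. Foxp3, the regulatory T cell lineage factor, rose from 12.6 ± 4.97 to 49.9 ± 4.63 CPM (SD, n = 3), a log2 fold change of 1.99 ± 0.29 (SE, adjusted p = 0.00872), with 26.4% of its sequence words shared with other genes. Il2ra, the IL-2 receptor alpha chain, rose from 490 ± 46.9 to 1558 ± 24.2 CPM (1.67 ± 0.08), and Lrrc32, which presents latent TGF beta on the cell surface, from 2.78 ± 1.30 to 29.5 ± 4.29 CPM (adjusted p = 0.00236). Of 17 regulatory T cell genes, 10 were higher, 0 lower and 7 not called, and 13 and 0 when adjusted over the list alone. The regulatory T cell list had a camera adjusted p = 5.32e-08, and an adjusted p = 0.461 with an estimated correlation. Stat3C replicate 5 had the highest value for 10 of the 17 genes, and without it the list median was 1.28 (adjusted p = 2.06e-07). Of 8 non-pathogenic TH17 genes, 5 were higher, 0 lower and 3 not called, and 6 and 0 when adjusted over the list alone. The non-pathogenic TH17 list had a camera adjusted p = 0.000520, and an adjusted p = 0.450 with an estimated correlation. In that list the IL-1 antagonist Il1rn rose from 2.96 ± 1.15 to 47.9 ± 23.1 CPM (4.02 ± 0.50, adjusted p = 0.00446) and Il10 from 1.37 ± 0.907 to 12.5 ± 5.96 CPM (3.19 ± 0.61, adjusted p = 0.0209). The Il10 call was lost without WT replicate 1, Stat3C replicate 5 or Stat3C replicate 6 (adjusted p = 0.0606, 0.0581 and 0.0513), and its log2 fold change was 3.86 without WT replicate 3.

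Early response genes, which T cells induce after receptor stimulation, were lower in Stat3C in part, 9 of 23. Egr3 went from 63 ± 8.34 to 9.37 ± 1.76 CPM (SD, n = 3) and fell by 2.75 ± 0.18 (SE) on the log2 scale (adjusted p = 0.000472). The orphan nuclear receptor genes Nr4a1, Nr4a2 and Nr4a3 were lower, with log2 fold changes of -1.86 ± 0.08, -2.44 ± 0.32 and -2.12 ± 0.14. Nr4a1 went from 358 ± 21.2 to 98.6 ± 5.08 CPM. Nfatc1, a calcium-regulated transcription factor, fell by 0.99 ± 0.09, from 251 ± 10.3 to 126 ± 13.9 CPM. Other members had positive values without a call, Egr1 0.84 ± 0.22 and Cd69 0.49 ± 0.13 (adjusted p = 0.0510 and 0.0535). Of 23 genes in the list, 0 were higher, 9 lower and 14 not called, and 2 and 9 when adjusted over the list alone. The early response list had a camera adjusted p = 0.000520, and an adjusted p = 0.491 with an estimated correlation. Its call was also lost with summed transcript reads.

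Targets of STAT3 and gp130 signalling, and receptors, rose in part. These lists also overlap with others. Hif1a and Il21 are both STAT3 targets and TH17 identity genes, and Il1r1 and Il23r are both cytokine receptor and TH17 identity genes. Timp1, an inhibitor of matrix metalloproteinases, rose from 5.0 ± 1.77 to 88.8 ± 19.2 CPM (SD, n = 3), a log2 fold change of 4.15 ± 0.33 (SE, adjusted p = 0.000997). Prdm1, which encodes Blimp-1, rose from 2.60 ± 0.716 to 20.9 ± 6.29 CPM. Hif1a rose by 1.14 ± 0.11 and the kinase gene Pim1 by 1.03 ± 0.12. Junb fell by 0.55 ± 0.07, a call lost with summed transcript reads (adjusted p = 0.343). Socs3, the feedback inhibitor of gp130 signalling, was at 154 ± 72.2 and 81.4 ± 16.1 CPM (-0.92 ± 0.38, adjusted p = 0.162), and its log2 fold change was 0.19 with summed transcript reads. Without WT replicate 2, Socs3 was called lower (-1.25, adjusted p = 0.0252). Of 28 genes in this list, 11 were higher, 1 lower and 16 not called, and 12 and 3 when adjusted over the list alone. The STAT3 target list had a camera adjusted p = 0.00193, and an adjusted p = 0.450 with an estimated correlation. Of the homing receptor genes Itgae, Ccr2 and Cxcr3 rose (3.12 ± 0.31, 3.27 ± 0.58 and 1.26 ± 0.13). Of 22 chemokine and homing receptor genes, 6 were higher, 2 lower and 14 not called, and 6 and 3 when adjusted over the list alone. The chemokine receptor list had a camera adjusted p = 0.00511, and an adjusted p = 0.598 with an estimated correlation. The decoy receptor gene Il1r2 and Il4ra rose (3.19 ± 0.51 and 0.99 ± 0.18). Of 30 JAK, STAT and cytokine receptor genes, 7 were higher, 2 lower and 21 not called, and 10 and 4 when adjusted over the list alone. The JAK and STAT list had a camera adjusted p = 0.0381, and an adjusted p = 0.581 with an estimated correlation. The chemokine call was lost without WT replicate 1 (adjusted p = 0.0503) and with a filter of 5 CPM. The JAK and STAT call was lost without WT replicate 1 or Stat3C replicate 5 (highest adjusted p = 0.123). It was also lost with filters of 1 and 5 CPM, with limma-voom with and without quality weights, and with limma-trend at a pseudocount of 0.1. In Stat3C replicate 5, 11 of the 22 and 11 of the 30 genes had their highest value.

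The list of pathogenic TH17 genes as a whole was not called (camera adjusted p = 0.0940), with a median log2 fold change of 0.68. It was called without WT replicate 3 (median 1.07, adjusted p = 0.0139) or Stat3C replicate 4 (0.81, adjusted p = 0.0412), and in 5 of 21 alternatives in all. Over all 21, called or not, the adjusted p values ran from 0.00145 to 0.797. The lowest of these, 0.00145, came from the mixed fry test, which asks for change in either direction. The directional fry test did not call the list (adjusted p = 0.201). Stat3C replicate 5 had the highest value for 11 of its 20 genes, and without it the median was 0.40 (adjusted p = 0.135). Of its 20 genes, 6 were higher, 2 lower and 12 not called, and 6 and 4 when adjusted over the list alone. Il7r rose from 7.03 ± 2.15 to 31 ± 7.96 CPM (SD, n = 3), a log2 fold change of 2.14 ± 0.28 (SE, adjusted p = 0.00543), and Gpr65 rose by 0.72 ± 0.06. Gpr65 is an acid-sensing receptor gene. Tbx21, which encodes the TH1 factor T-bet, fell by 1.67 ± 0.11, from 101 ± 8.19 to 31.6 ± 3.74 CPM (adjusted p = 0.000539). Csf2, the GM-CSF gene, was at 1.64 ± 0.858 and 2.28 ± 0.920 CPM (0.47 ± 0.48, adjusted p = 0.555). Ifng was at 18.2 ± 10.6 and 25.4 ± 18 CPM (0.49 ± 0.61, adjusted p = 0.640), and its log2 fold change was -0.26 without Stat3C replicate 5. Of 19 TH1 and cytotoxic genes, 3 were higher, 3 lower and 13 not called, and 4 and 3 when adjusted over the list alone (camera adjusted p = 0.809). In that list Cxcr3 rose by 1.26 ± 0.13, and Eomes fell by 2.18 ± 0.26, from 2.85 to 0.629 CPM.

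Surface receptor genes of other T cell programmes moved both ways. Tigit, a coinhibitory receptor gene, rose from 17.8 ± 2.33 to 85.4 ± 5.75 CPM (SD, n = 3), a log2 fold change of 2.26 ± 0.12 (SE, adjusted p = 0.000212), and Ctla4 rose by 1.39 ± 0.15. Of 13 coinhibitory receptor genes, 2 were higher, 3 lower and 8 not called, and 3 and 4 when adjusted over the list alone (camera adjusted p = 0.297). Slamf6, a receptor of the SLAM family, fell by 2.47 ± 0.13, from 160 ± 9.16 to 28.8 ± 4.35 CPM (adjusted p = 0.000191). Of 13 follicular helper genes, 3 were higher, 2 lower and 8 not called, and 5 and 5 when adjusted over the list alone (camera adjusted p = 0.853). Among 16 naive and memory genes, 6 were higher, 1 lower and 9 not called, and 6 and 3 when adjusted over the list alone (camera adjusted p = 0.0660). Without WT replicate 3 that list was called (adjusted p = 0.0331). Satb1 rose by 0.93 ± 0.08 and Foxo1 by 0.73 ± 0.07. In store-operated calcium entry, the channel gene Orai1 fell by 1.00 ± 0.09, from 57.0 ± 1.16 to 28.5 ± 2.63 CPM (adjusted p = 0.00135). Of the 20 genes in that list, 4 were higher, 3 lower and 13 not called, and 6 and 5 when adjusted over the list alone (camera adjusted p = 0.853).

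Metabolic and housekeeping groups moved both ways. The glycolytic enzyme genes Hk2 and Pkm rose by 0.50 ± 0.06 and 0.40 ± 0.07 (SE), whereas the more abundant Gapdh and Eno1 were lower. Gapdh went from 11860 ± 2853 to 6812 ± 376 CPM and Eno1 from 4803 ± 421 to 3721 ± 64.3 CPM (SD, n = 3), with log2 fold changes of -0.80 ± 0.16 and -0.37 ± 0.07. Of 20 glycolysis genes, 5 were higher, 2 lower and 13 not called, and 8 and 3 when adjusted over the list alone. The glycolysis list had a camera adjusted p = 0.0447, and an adjusted p = 0.450 with an estimated correlation. Bnip3, a mitophagy gene in that list, rose from 11 ± 4.27 to 51.7 ± 3.69 CPM (SD, n = 3), with 57.0% of its sequence words shared with other genes. Of 13 mitochondrially encoded genes, 0 were higher, 7 lower and 6 not called, and 1 and 7 when adjusted over the list alone. The mitochondrially encoded list had a camera adjusted p = 0.000763, and an adjusted p = 0.629 with an estimated correlation. In that list mt-Atp8 fell by 1.29 ± 0.09 (SE) on the log2 scale, from 297 ± 10.3 to 122 ± 11.3 CPM, and mt-Atp6 fell by 1.09 ± 0.08. Over the list a median of 62.8% of sequence words was shared with other genes. Of 24 cholesterol synthesis genes, 0 were higher, 4 lower and 20 not called, and 0 and 11 when adjusted over the list alone. The cholesterol list had a camera adjusted p = 0.000763, and an adjusted p = 0.629 with an estimated correlation. The kinase gene Pmvk fell by 0.90 ± 0.15, from 53.3 ± 2.14 to 28.5 ± 5.78 CPM. Of 30 ribosomal protein genes, 0 were higher, 6 lower and 24 not called, and 1 and 10 when adjusted over the list alone. The ribosomal list had a camera adjusted p = 0.00826, and an adjusted p = 0.797 with an estimated correlation. Rps23 fell by 1.29 ± 0.09. The glycolysis call was lost without WT replicate 1, WT replicate 2 or Stat3C replicate 6 (highest adjusted p = 0.0876). It was also lost with upper quartile scaling, with filters of 1 and 5 CPM, and with coding genes of little shared sequence. The Gapdh call was lost without WT replicate 3 or any 1 Stat3C replicate, and the Eno1 call also without WT replicate 1 (highest adjusted p = 0.0998 and 0.0771). The ribosomal call was lost without Stat3C replicate 5 (adjusted p = 0.0784), with the directional fry test (adjusted p = 0.0647), with summed transcript reads and with coding genes of little shared sequence. Its median log2 fold change was -0.20, and -0.015 with summed reads, and a median of 29.9% of sequence words was shared with other genes. The Pmvk call was lost without WT replicate 3 or Stat3C replicate 4 (highest adjusted p = 0.0571).

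**Figure D2:**
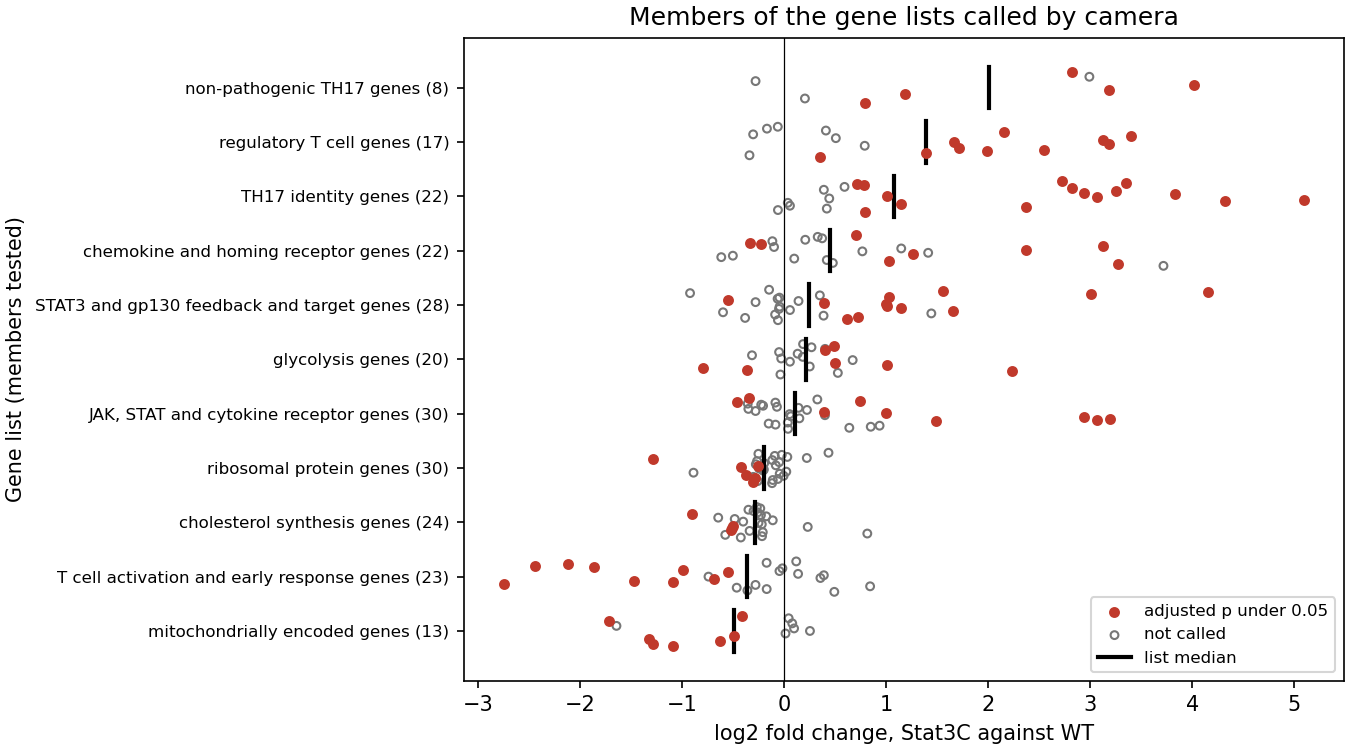
Log2 fold change of Stat3C against WT (horizontal axis) for the members of the 11 gene lists called by camera (vertical axis), with filled points for genes at an adjusted p under 0.05, open points for the rest and a black bar at the list median. In the TH17 identity list 15 of 22 genes were called higher and 0 lower, and in the early response list 0 higher and 9 lower. With a correlation estimated per list, 0 of the 11 lists were called.

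The genes with the largest rises included several outside the TH17 lists. Enpp2, which encodes autotaxin, rose from 0.501 ± 0.104 to 44.1 ± 27.4 CPM (SD, n = 3), a log2 fold change of 6.46 ± 0.55 (SE, adjusted p = 0.00123). The proton pump subunit gene Atp6v0d2 rose by 5.74 ± 0.40 and the natriuretic peptide clearance receptor gene Npr3 by 5.56 ± 0.77. Serpinb5, Crispld2, Serpinb1a, Ppp1r9a and Lrrc25 rose by 5.38 ± 0.61, 5.30 ± 0.59, 7.20 ± 1.02, 6.09 ± 1.47 and 4.73 ± 0.89. These 5 genes had only 69, 38, 12, 11 and 82 counts over the WT libraries, and Atp6v0d2 and Npr3 had 17 and 18. Over all alternatives the lowest log2 fold changes of the 5 were 3.65, 2.96, 3.12, 2.16 and 3.22. Those of Atp6v0d2 and Npr3 were 2.56 and 2.32, so the size of these rises depends on the method. Without Stat3C replicate 5 the log2 fold changes of Enpp2, Npr3 and Serpinb1a were 5.83, 4.96 and 5.95. Without WT replicate 3 those of Npr3, Crispld2 and Lrrc25 were 6.18, 6.14 and 6.46. That of Serpinb5 was 5.97 without WT replicate 1. That of Ppp1r9a was 7.72, 5.42 and 5.06 without WT replicate 1, WT replicate 2 and Stat3C replicate 6. Ly6g, a neutrophil surface antigen gene, had 2 counts over the WT libraries and a Stat3C mean of 11.8 ± 8.25 CPM (adjusted p = 0.00229), at 6.42, 21.3 and 7.62 CPM in replicates 4, 5 and 6. The basophil protease gene Mcpt8 had 4 counts over the WT libraries and stood at 0.961, 29.6 and 0.577 CPM in Stat3C replicates 4, 5 and 6 (adjusted p = 0.0498). Stat3C replicate 5 was also the highest library for 8 of 9 tested myeloid marker genes. Of these 9 genes, 2 were higher, 0 lower and 7 not called, with the same counts when adjusted over the list alone (camera adjusted p = 0.0523). The called genes were Cd68 and Mpeg1, and both calls were lost whichever library was left out (highest adjusted p = 0.0978 and 0.141). The myeloid list was called without WT replicate 3, Stat3C replicate 4 or Stat3C replicate 6 (adjusted p = 0.0316, 0.0412 and 0.00536), and its median went from 1.06 to 0.035 without Stat3C replicate 5. With single libraries left out, the call of Mcpt8 held only without Stat3C replicate 6. That of Ppp1r9a held without WT replicate 1 or Stat3C replicate 5, and that of Lrrc25 without WT replicate 1 or 3. The highest adjusted p of these fits were 0.148, 0.129 and 0.0620, and the Serpinb1a call was lost with limma-voom. Pgk1-rs7, a processed pseudogene, was at 0 in WT and 38.1 ± 14.2 CPM in Stat3C, at least 2193-fold higher against a floor of 3 counts over the group. Its sequence words were 100% shared with other genes. Over all alternatives its lowest log2 fold change was 5.22, so the size of this rise depends on the method too.

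Of the 12 largest falls, 9 were in genes with over 10% of their sequence words shared with other genes. Hist1h2aj, a histone pseudogene, went from 88.4 ± 33.4 CPM to 0 (SD, n = 3), at least 3969-fold lower against a floor of 3 counts over the group, and the histone gene Hist1h2bq from 93.0 ± 23.1 CPM to 3 counts over the Stat3C libraries. The smallest change of Hist1h2aj over all alternatives was a log2 fold change of -6.40, so its size depends on the method. Hist1h2ai, Hist1h4a, Hist1h3b and Hist1h2bb fell, with log2 fold changes of -7.58 ± 0.76, -5.33 ± 0.60, -4.81 ± 0.23 and -4.72 ± 0.46 (SE). Without Stat3C replicate 4 that of Hist1h2ai was -8.25. In the order named, the 6 histone genes shared 93.5%, 98.3%, 92.0%, 47.9%, 61.9% and 47.7% of their sequence words with other genes. Mettl7a3, Zfp967 and Olfr344 fell too, with log2 fold changes of -4.84 ± 0.31, -4.24 ± 0.31 and -4.21 ± 0.49 and 62.4%, 100% and 24.7% shared. With at most 10% shared, the GTPase gene Rab34 fell by 8.15 ± 0.11, from 151 ± 11.7 to 0.536 ± 0.0357 CPM. Rep15 and Fmo1 also fell (-5.42 ± 0.21 and -4.48 ± 0.48). The next falls were selected among coding genes with at most 10% shared after the values were seen. The microtubule protein gene Map4 fell by 3.45 ± 0.20, from 2613 ± 159 to 239 ± 64.1 CPM. The macrophage lectin gene Siglec1 fell by 3.46 ± 0.25, from 127 ± 10.8 to 11.6 ± 3.94 CPM. Myeloid markers had medians of only 0.156, 0.0632 and 0.167 CPM in WT replicates 1, 2 and 3. The fall of Siglec1 is therefore not evidence of macrophages lost in Stat3C. Lower too were Fstl1 (-4.06), Lhfpl4 (-3.99), Klf12 (-3.82), Myo7a (-3.49), Chd9 (-3.35), Fn1 (-3.11) and Col5a3 (-3.01). The same selection of rises added Upp1 (4.31 ± 0.46, and 4.95 without WT replicate 3). With summed transcript reads the falls were smaller for Rab34 (-4.52), Map4 (-2.70) and Myo7a (-0.62).

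Long noncoding and pseudogene transcripts made up less of the Stat3C libraries. Genes annotated as lincRNA held 4.98% ± 0.368 of counts in WT and 0.964% ± 0.0148 in Stat3C (SD, n = 3, exact two-sided permutation p = 0.1). Of 619 tested lincRNA genes, 21 were higher and 117 lower, and of 932 pseudogenes, 27 and 81. Protein-coding genes with at most 10% shared sequence gave 774 higher and 495 lower of 9676, whereas those with over 50% shared gave 25 and 121 of 632. When the genes with at most 10% shared were scaled and fitted on their own, 626 were higher and 611 lower. In the main fit the median log2 fold change was 0.08 over the 5635 genes with up to 1% shared and -0.40 over the 757 with 80% or more.

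**Figure D3:**
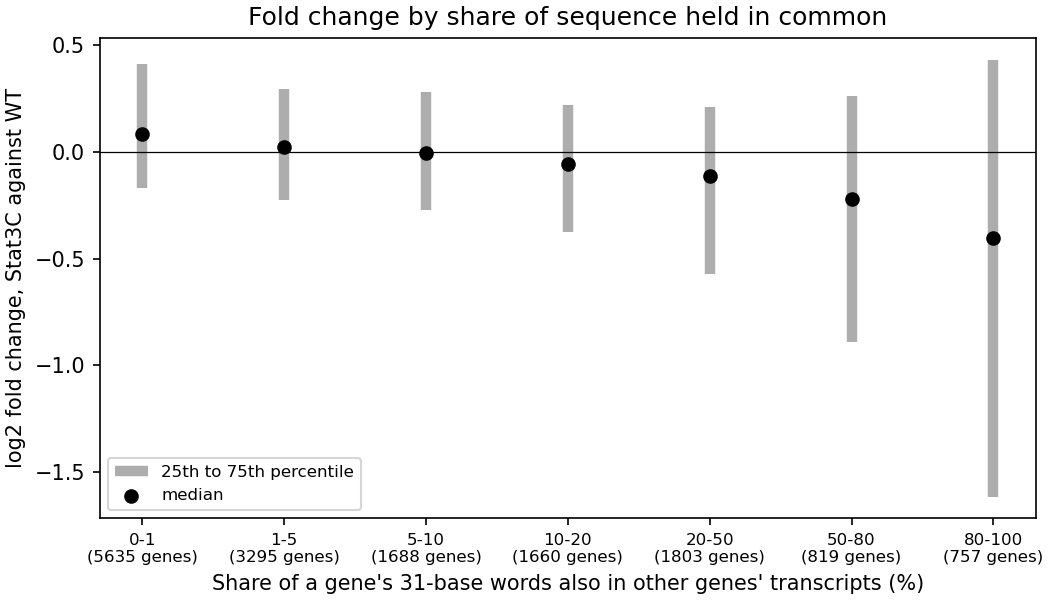
Median log2 fold change of Stat3C against WT (points) and the 25th to 75th percentile (bars) for genes grouped by the percentage of their 31-base words found in transcripts of other genes. The median was 0.08 in the group with the least shared sequence and -0.40 in that with the most.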

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

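The fit on protein-coding genes with little shared sequence was chosen only after the results were seen, and all other alternatives were fixed beforehand. Stat3 kept its direction and its call in all 18 alternatives that gave it a value, with log2 fold changes from 1.25 to 2.16. Of the 138 named genes that were called, 89 kept direction and call in every alternative that tested them, 49 lost the call in at least 1, and 3 changed sign. Of the 11 called lists, 0 kept the call with an estimated correlation, and 6 kept it under every other alternative, namely the TH17 identity, regulatory T cell, non-pathogenic TH17, STAT3 target, mitochondrially encoded and cholesterol lists. The early response list lost its call also with summed transcript reads. Of the lists not called, 15 were called in at least 1 alternative, most often the stress response (10 of 21), heat shock (8 of 21), myeloid (8 of 20), naive and memory (6 of 21) and pathogenic TH17 lists (5 of 21). The alternatives include the mixed fry test, which asks for change in either direction. It alone called the TH1, follicular helper, store-operated calcium entry, proliferation, oxidative phosphorylation, negative regulator and NK lists.

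The number of genes called, 2192 (984 higher and 1208 lower), became 3562 (1740 and 1822) with DESeq2, 3818 (1925 and 1893) with summed transcript reads, 817 (332 and 485) at an adjusted p under 0.01, 1125 (438 and 687) with a fold of at least 2, 1289 (526 and 763) with glmTreat, and 1237 (626 and 611) with coding genes of little shared sequence. The last 4 differ in number by construction, through a stricter threshold or fewer genes. In the main fit the same coding genes of little shared sequence gave 774 higher and 495 lower. Fewer genes alone therefore do not account for the more even 626 and 611, and that fit was also scaled on those genes alone. For DESeq2 and summed reads the cause was not tested. With 1 library left out the number called ranged from 1201 to 2013, the higher ones from 500 to 994 and the lower ones from 633 to 1019, with fewer samples in each fit. The number of lists called was 18 with DESeq2, 0 with an estimated correlation, 23 with the mixed fry test, which asks for change in either direction, and 8 to 15 with 1 library left out. The fit without a low count filter tested 28985 genes and called 1709. The largest shift of the median log2 fold change over genes was -0.05, with coding genes of little shared sequence.

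Some values changed sign, and where fewer samples or genes do not show the cause, the cause was not tested. With summed transcript reads the log2 fold changes were 0.11 for Cox6a1, 0.043 for Rpl13, -0.28 for Hspa8 (called in either fit) and 0.19 for Socs3, and list medians were -0.034 for proliferation, 0.0035 for oxidative phosphorylation and -0.011 for sex-linked genes. At 5 CPM the medians were -0.061 for TH2 genes and -0.011 for negative regulators of cytokine signalling. With voom quality weights they were -0.059 for negative regulators, -0.20 for interferon-stimulated genes and -1.04 for erythroid and platelet markers. With a pseudocount of 0.1 they were -0.35 for erythroid and platelet markers and 0.031 for gamma delta T cell markers, and with coding genes of little shared sequence -0.045 for store-operated calcium entry and 0.35 for gamma delta markers. With 1 library left out, Ifng ranged from -0.26 to 1.03, and medians from -0.052 to 0.20 for negative regulators, -0.29 to 0.81 for sex-linked genes, -0.54 to 0.51 for gamma delta markers, -0.050 to 0.44 for follicular helper genes, -0.21 to 0.62 for TH1 genes, -0.31 to 0.65 for interferon-stimulated genes and -3.95 to 2.49 for erythroid and platelet markers. No paired analysis was possible because no replicate number was shared between the groups. A fit that accounts for sex was not run, although Xist was high only in WT replicate 3 and Stat3C replicate 6. Depth limits the genes near 1 count, which was 0.0385 CPM in Stat3C replicate 6.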

Other observations

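Tests of length scaling, of the Stat3 explanations and of basophil and mast cell markers in all Stat3C cultures were chosen only after the results they concern had been seen, as was the use of quartiles in the test of myeloid markers. Some stress response genes were lower in Stat3C. Trib3 and Asns, stress response targets of ATF4, fell by 1.30 ± 0.24 and 0.79 ± 0.11 (SE, n = 3 per group) on the log2 scale, the Trib3 call being lost without WT replicate 2, WT replicate 3, Stat3C replicate 4 or Stat3C replicate 5 (highest adjusted p = 0.0690). In the unfolded protein and integrated stress response list 0 of 22 genes were higher, 3 lower and 19 not called, and 0 and 3 when adjusted over the list alone (camera adjusted p = 0.0571). That list was called in 10 of 21 alternatives, among them the fit without Stat3C replicate 6 (adjusted p = 0.0309). Over all 21, called or not, its adjusted p ran from 0.00183 to 0.629. Its lowest adjusted p, 0.00183, came from the mixed fry test, which asks for change in either direction. The directional fry test gave an adjusted p = 0.0267. Hspa1b, an inducible heat shock gene, fell by 1.85 ± 0.20, and of 11 heat shock genes 1 was higher, 2 lower and 8 not called, and 1 and 2 when adjusted over the list alone (adjusted p = 0.0660). The heat shock list was called in 8 of 21 alternatives, among them the fit without Stat3C replicate 4 (adjusted p = 0.0412). Over all 21, called or not, its adjusted p ran from 0.000540 to 0.648. Its lowest adjusted p, 0.000540, also came from the mixed fry test, and the directional fry test gave an adjusted p = 0.0445. Top2a, a topoisomerase of dividing cells, rose by 0.49 ± 0.05, but of 30 proliferation genes 1 was higher, 1 lower and 28 not called, and 1 and 0 when adjusted over the list alone (adjusted p = 0.378). Of 32 oxidative phosphorylation genes 0 were higher, 2 lower and 30 not called, and 0 and 0 when adjusted over the list alone (adjusted p = 0.514). Of 17 negative regulators of cytokine signalling 2 were higher, 1 lower and 14 not called, with the same counts when adjusted over the list alone (adjusted p = 0.853).

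Interferon-stimulated genes, TH2 genes and markers of other cells were not called as lists, and several were highest in Stat3C replicate 5. Of 28 interferon-stimulated genes 0 were higher, 2 lower and 26 not called (adjusted p = 0.853), and Irf7 stood at 14.1 CPM in Stat3C replicate 5 against 1.15 and 0.769 CPM in Stat3C replicates 4 and 6. Of 8 MHC class II genes 0 were called (adjusted p = 0.111), with H2-Aa at 28.3 CPM in Stat3C replicate 5 against 2.08 and 3.65 CPM in the other Stat3C libraries. Of 10 TH2 genes and 12 B cell markers 0 were called (adjusted p = 0.341 and 0.312), and B cell markers were highest in Stat3C replicate 5 for 2 of 12. The MHC class II list was called without Stat3C replicate 4 and the B cell list without WT replicate 3 (adjusted p = 0.0139 and 0.0190). Of 6 markers of NK and innate-like lymphocytes 0 were higher, 1 lower and 5 not called (adjusted p = 0.796). Of 7 gamma delta T cell, 4 sex-linked and 4 erythroid and platelet genes 0 were called (adjusted p = 0.973, 0.899 and 0.904). Of 9 detected erythroid and platelet markers, 9 were highest in Stat3C replicate 5, with Hbb-bt at 84.7 CPM and Pf4 at 6.86 CPM there. Globin transcripts were also present in WT replicate 1, with Hbb-bs at 8.24 and Hbb-bt at 8.39 CPM, while Stat3C replicate 4 held Hbb-bt at 0.635 CPM. Adjusted over each list alone, these 8 lists gave the same counts. The CD8 T cell list had too few genes for a test, and Cd8a averaged 4.93 ± 3.10 CPM in WT and 5.37 ± 2.09 CPM in Stat3C (SD, n = 3).

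Transcripts of lincRNA and pseudogene class were more often called lower than higher in Stat3C, 198 and 48 of 1551 genes. Length scaling alone would leave unscaled reads even, but lincRNA transcripts took 5.65% of unscaled reads in WT and 1.08% in Stat3C, a ratio of 5.25, which argues against it for the lincRNA share of reads. That share is a total, so it does not test the calls of single genes, and pseudogenes were not tested in this way. With summed unscaled reads, 1925 genes of all classes were called higher and 1893 lower. Reads shared with paralogs, pseudogenes or repeats may contribute, since lincRNAs and pseudogenes with over 50% shared sequence had a median log2 fold change of -0.22 against 0.12 for those with at most 1%, a difference of -0.34 that did not reach the 0.5 set beforehand. With over 50% shared 23 were higher and 90 lower of 666, and with at most 1% shared 9 were higher and 3 lower of 153, so that 13.5% and 1.96% were called lower (Fisher's exact two-sided test across genes, which are not independent replicates, p = 6.75e-06). A difference in library handling between genotypes cannot be told apart from the genotype, since no label gives a batch, and the biological explanation, active STAT3, was not tested separately.

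Stat3 reads were higher in Stat3C, and their distribution over transcript models differed. A higher level of the endogenous transcripts alone would leave the distribution as in WT. Models without a 3' UTR of at least 1000 bases gained 33.4 percentage points of Stat3 reads. This argues against it only if the libraries of both groups otherwise spread reads over models alike, which was not checked in other genes. Rab34 and Myo7a changed by -8.15 and -3.49 with length scaling but by -4.52 and -0.62 with summed reads. Reads of an inserted Stat3 coding sequence are a candidate explanation, since the lowest Stat3C library lay 27.9 percentage points above the highest WT library. Gt(ROSA)26Sor, annotated as antisense, was also lower in every Stat3C library. The lincRNA share of counts fell as well, from 4.98% in WT to 0.964% in Stat3C. A wider fall of noncoding transcripts is therefore not told apart from an insertion at that locus. Long-UTR models were also 1.84 times as high in TPM, so an added change in the endogenous transcript stays open, and a vector sequence was not analysed here.

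Myeloid and granulocyte transcripts stood out in Stat3C replicate 5. Cells of another type in that culture are a candidate explanation, since 11 of 11 basophil and mast cell markers were highest there, at a median 22.3 times the mean of the other 5 libraries, with Gata2 at 95.5 and Prss34 at 24.7 CPM, and so were 6 of 9 neutrophil markers (6.45 times) and 9 of 9 erythroid and platelet markers. The neutrophil ratio rests in part on genes near the floor. In Stat3C replicate 5, S100a8, Csf3r, S100a9 and Mmp8 stood at 0.238, 0.238, 0.139 and 0.139 CPM. The neutrophil markers Cxcr2 and Lcn2 reached 3.77 and 2.875 CPM there. A change of like size in all Stat3C cultures is argued against by the fixed myeloid list, whose median ratio to WT was 1.00 (quartiles 0.829 and 2.05) in Stat3C replicates 4 and 6 and 7.93 in Stat3C replicate 5, and by the basophil and mast cell markers, at 3.32 (quartiles 1.43 and 6.57) and 28.4. A smaller rise in all Stat3C cultures stays open, since 7 of 11 basophil and mast cell markers were above all WT libraries in both replicates 4 and 6, and Cd68 was at 5.44 and 5.39 CPM there, near its 5.85 CPM in Stat3C replicate 5 and above its WT mean of 3.08 ± 0.374 CPM. In the basophil and mast cell and the neutrophil list 3 and 1 members reached 1 CPM in other libraries and 0 and 2 were also in lists fixed beforehand, and expression of these genes by the T cells themselves was not tested.

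Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 2192 genes and the highest other split 10, so that 1 split reached the real number. It called 11 lists, and the highest other split, WT replicates 1 and 2 with Stat3C replicate 4 against the rest, called 14, so that 3 splits reached the real number.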
